A study of Mus musculus with 56 samples.

How the data were processed

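RNA-seq of the hippocampus was analysed for 56 mice, each sequenced once, in 4 groups taken from the labels: WT on vehicle (n = 19), Hexb-/- on vehicle (n = 11), Hexb-/- on sinbaglustat 30 mg/kg/day (n = 14) and Hexb-/- on 300 mg/kg/day (n = 12). Per the labels' protocols, tissue was kept in RNAlater, RNA was extracted with TRI Reagent and magnetic beads, and poly(A) libraries were made with the Universal Plus mRNA-Seq kit. The authors deposited 1 table of raw counts per gene; per the submitters' processing notes, reads were aligned with STAR 2.5 to GRCm38 and counted with featureCounts. The annotation release and the strand setting are not stated. The table has 36489 genes, none without a symbol. Of their symbols, 35480 were found in the GENCODE M21 annotation, which gave gene identifiers and coordinates, and 16729 of 16909 tested ones were.

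Library totals ranged from 15.6 to 44.0 M counts. Choices stated here without other wording were made before the data were examined. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 16909. Counts were normalized with TMM (factors 0.974 to 1.036) and fitted with edgeR 4.0.16 (quasi-likelihood, robust, 1 mean per group, all 56 libraries, 52 residual degrees of freedom). In all, 6 comparisons were tested, with Benjamini-Hochberg adjustment over the tested genes of each, and genes under an adjusted p of 0.05 were called. Log2 fold changes and SE come from this fit, and CPM values are TMM-scaled, as mean ± SD over mice. Simulated changes were given to 200 genes in each comparison. Between Hexb vehicle and WT, 46% of those changed 1.15-fold and 92% of those changed 2-fold were recovered. Between 30 mg/kg and vehicle the shares were 38% and 84%. Of the calls, 4 of 142 and 5 of 128 were false. Recovery depends on how many genes are called, so these shares do not carry over to comparisons with few calls.

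Before the data were examined, 33 gene lists with 485 distinct genes were written down for cell types and processes. Each was tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with the correlation estimated from the data and with fry. Adjusted p-values of lists are over the 33 lists of a comparison, and "adjusted over the list alone" means the edgeR p-values of its members adjusted among themselves. List scores per mouse are the mean log2 CPM of a list's tested members. Their group differences were tested by two-sided permutation of mice (100000 resamples, so 1e-05 is the smallest p they can give) and adjusted over 198 tests. The position between WT and Hexb vehicle used 100 partitions of the controls. In each partition limma picked genes in 10 WT and 5 vehicle mice, and scores used the other 9 WT and 6 vehicle mice, with 20 bootstraps per partition. On simulated mice at 0.9 and 0.5 it returned 0.883 ± 0.0861 and 0.491 ± 0.0577 (SD).

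Genes to be named were also set by rule. They are Hexb, Hexa, Gm2a, Gba, Gba2 and Ugcg, then the 10 largest rises and 10 largest falls among called genes with at least 1 CPM in 1 of the groups (without predicted symbols), and up to 4 members per list with the smallest adjusted p between Hexb vehicle and WT. Genes called at a dose with the sign opposite to that of Hexb vehicle against WT were also named. Exceptions are stated where they occur.

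Comparisons that share control mice were set against simulated groups without an effect and against fits with the shared mice split. Correlations of fold changes used 100 simulations and 50 splits. Shares of signs and overlaps of calls used 50 simulations, and those against WT used 20 splits. Within each group, pairs of libraries were checked for duplicates. Alternatives were the DESeq2 1.42.0 Wald test, limma-voom with quality weights, other scaling, other filters, fits of only the compared groups, covariates and left-out libraries. Surrogate variables (sva 3.50.0), a factor for depth, fits within the shallower or the deeper libraries, and fits without libraries of high choroid plexus score, without WT 13B2 or without 8 libraries high in Gh or Prl were added after seeing the data. Those 8 lay over 16 CPM of either gene once the prior count was included. Among them 12E2 had 14.6 CPM of Gh and 15.9 of Prl without it. Sex is not in the labels and was followed by the ratio of Xist to Ddx3y. Scripts ran in R 4.3.3 and Python 3.11.15 (matplotlib 3.10.9).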

Results

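Poly(A) RNA was sequenced from the hippocampus of 56 individual mice in 4 groups. The groups were 19 wild-type (WT) mice given vehicle, 11 Hexb-/- mice given vehicle, 14 Hexb-/- mice given sinbaglustat at 30 mg/kg/day and 12 Hexb-/- mice given 300 mg/kg/day. Hexb encodes the beta subunit of the lysosomal beta-hexosaminidases. Without it GM2 ganglioside is not broken down, as in Sandhoff disease, and Hexb-/- mice are a model of that disease. Sinbaglustat is an orally given iminosugar. Per the labels, the lower dose was meant mainly to inhibit the non-lysosomal glucosylceramidase GBA2, and the higher dose to inhibit GBA2 and also glucosylceramide synthase (GCS, encoded by Ugcg), the first enzyme of the glucosphingolipid pathway. Compound or vehicle was mixed into the feed from week 4 to week 15.

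Libraries held 15.6 to 44.0 M counts, with medians of 18.6 M in WT, 18.3 M in Hexb vehicle, 17.9 M at 30 mg/kg and 17.4 M at 300 mg/kg. Totals fell into 2 clusters, 37 libraries of at most 20042194 counts and 19 of at least 24361584, and each group had libraries in both. The shallower cluster held 12 WT, 8 Hexb vehicle, 9 30 mg/kg and 8 300 mg/kg libraries. The deeper cluster held 7, 3, 5 and 4 in the same order. Of 36489 genes counted, 16909 had enough counts to be tested, and the biological coefficient of variation between mice of a group was 13.8%. Each prefix of the animal codes (such as 9C) but 11F holds mice of 1 group, and the labels do not say what prefixes mark. Prefix is thus nested in group, so differences between prefixes can enter every group difference. The library index also runs mostly by group, and its part was not tested. With the prefix as a random effect (correlation between mice of a prefix 0.0779) limma-voom called 1702 genes between Hexb vehicle and WT, 1359 and 873 at 30 and 300 mg/kg against WT, 4 between the doses, and 0 at either dose against Hexb vehicle (1069 and 610 at an unadjusted p under 0.05). No pair of libraries within a group was identical, and the closest of 383 such pairs differed by a chi-square of 2.96 per gene, above sampling noise. Choroid plexus RNA varied between libraries. The mean log2 CPM (counts scaled to library size) of a choroid plexus marker list exceeded 3 in 12 libraries, 4 of them WT, 4 Hexb vehicle and 2 at each dose, and its mean was 1.59 ± 1.56 in WT, 2.44 ± 2.0 in Hexb vehicle, 1.76 ± 1.5 at 30 mg/kg and 2.16 ± 1.75 at 300 mg/kg (SD). The WT mouse 13B2 stood apart on a thalamus and striatum marker list, with a score of 5.22 against at most 3.45 in the other libraries.

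Hexb itself was low in every Hexb-/- library. It measured 93.8 ± 7.20 CPM in WT (SD, n = 19), 12.3 ± 1.43 in Hexb vehicle (n = 11), 11.7 ± 1.47 at 30 mg/kg (n = 14) and 11.5 ± 1.46 at 300 mg/kg (n = 12), or 13.2%, 12.5% and 12.2% of the WT mean. The ranges did not meet, with 80.2 CPM the lowest WT value and 15.7 the highest among Hexb vehicle mice. The fall in Hexb vehicle was 7.62-fold (log2 -2.93, SE 0.0624, edgeR adjusted p = 4.96e-44). Hexb (ENSMUSG00000021665.9) lies on chromosome 13 from 97176331 to 97198357, on the minus strand, in GRCm38, and its longest annotated transcript has 14 exons. The 3' part of Hexb overlaps the end of Gfm2, a mitochondrial translation factor gene on the same chromosome (97137937 to 97181195), and the strand setting of the counting is not stated, so where reads of the overlap were counted is unknown.

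**Figure D1:**
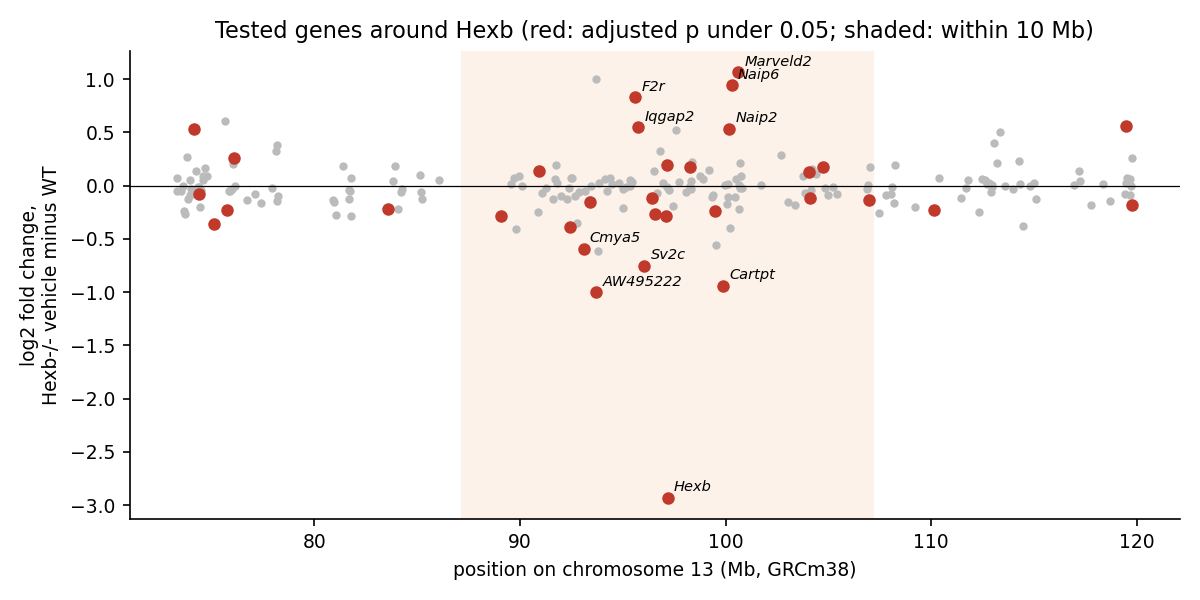
Log2 fold change of Hexb vehicle against WT for each tested gene around Hexb on chromosome 13, by position; red points pass an edgeR adjusted p of 0.05, and shading marks 10 Mb on either side of Hexb.

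The first comparison asked what loss of Hexb does to the hippocampal transcriptome in vehicle-fed mice. Genes that work beside Hexb in ganglioside breakdown rose. Hexa, the alpha subunit of the same enzymes, measured 64.2 ± 5.07 CPM in Hexb vehicle and 48.6 ± 3.36 in WT (SD, n = 11 and 19; log2 0.40, SE 0.0383, edgeR adjusted p = 2.02e-12). Gm2a, the GM2 activator protein, rose by 0.24 on the log2 scale (adjusted p = 6.6e-07) and Gba, the lysosomal glucocerebrosidase, by 0.20 (adjusted p = 4.04e-05). All 11 Hexb vehicle mice lay above the WT median for each of these 3 genes. The genes of the drug targets did not pass the test: Gba2 differed by log2 -0.02 (adjusted p = 0.714) and Ugcg by -0.07 (adjusted p = 0.295). The lysosome list, which holds these enzymes, cathepsins and membrane proteins, had the smallest camera p of the 33 lists. Of its 43 measured members 34 rose and none fell (37 and 0 adjusted over the list alone), among them the cathepsin Ctss (log2 0.81, adjusted p = 1.41e-21), the mannosidase Man2b1 (0.47, 1.18e-18) and the progranulin gene Grn (0.48, 1.18e-16). The camera test gave adjusted p = 6.58e-50 for the list, and adjusted p = 3.19e-06 with an estimated correlation.

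Genes of activated microglia rose steeply. Cst7, a cathepsin inhibitor, went from 0.190 ± 0.150 CPM in WT to 3.18 ± 0.980 in Hexb vehicle, a 16.8-fold rise (log2 4.07, SE 0.244, edgeR adjusted p = 8.08e-21). Trem2, a lipid-sensing microglial receptor, rose from 9.93 ± 0.764 to 22.6 ± 3.30 CPM (log2 1.19, SE 0.0535, adjusted p = 1.67e-26). Cd68, a phagocyte lysosomal membrane protein, rose from 11.6 ± 1.41 to 29.0 ± 3.62 (log2 1.31, adjusted p = 4.53e-26), and Tyrobp, the signalling adaptor of Trem2, by log2 1.13 (adjusted p = 2.26e-24). All 11 Hexb vehicle mice lay above the WT median for each of these genes. Of 23 measured disease-associated microglia genes, 16 rose and none fell (18 and 0 adjusted over the list alone; camera adjusted p = 1.23e-36, and 1.18e-06 with an estimated correlation). The immune receptor genes Ly9 (log2 3.26, adjusted p = 3.67e-20), Cd22 (2.92, 1.34e-17), Clec7a (2.28, 9.86e-12) and Treml2 (2.19, 6.26e-12) were also among the 10 largest rises.

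Complement and cytokine genes rose as well. Of 16 complement and phagocytic receptor genes, 13 rose and none fell (14 and 0 adjusted over the list alone; camera adjusted p = 8.43e-37, and 1.18e-06 with an estimated correlation). C1qb, a chain of the complement initiator C1q, measured 80.4 ± 6.91 CPM against 41.3 ± 3.16 in WT (log2 0.96, SE 0.049, edgeR adjusted p = 4.98e-24). C1qc (log2 0.82, adjusted p = 4.55e-22), C1qa (0.95, 7.72e-22) and the anaphylatoxin receptor C3ar1 (1.17, 4.07e-17) followed. Of 13 cytokine and chemokine genes 5 could be measured and all 5 rose (5 also adjusted over the list alone), among them the chemokines Ccl3 (log2 2.5, adjusted p = 1.96e-09), Cxcl10 (1.77, 0.000104) and Cxcl16 (0.83, 0.000393) and the interleukin Il1a (0.94, 0.00122); the list passed camera (adjusted p = 4.43e-07, and 0.00021 with an estimated correlation). These 2 lists, with lysosome and disease-associated microglia, were the 4 of 33 whose camera calls held with an estimated correlation in this comparison.

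**Figure D2:**
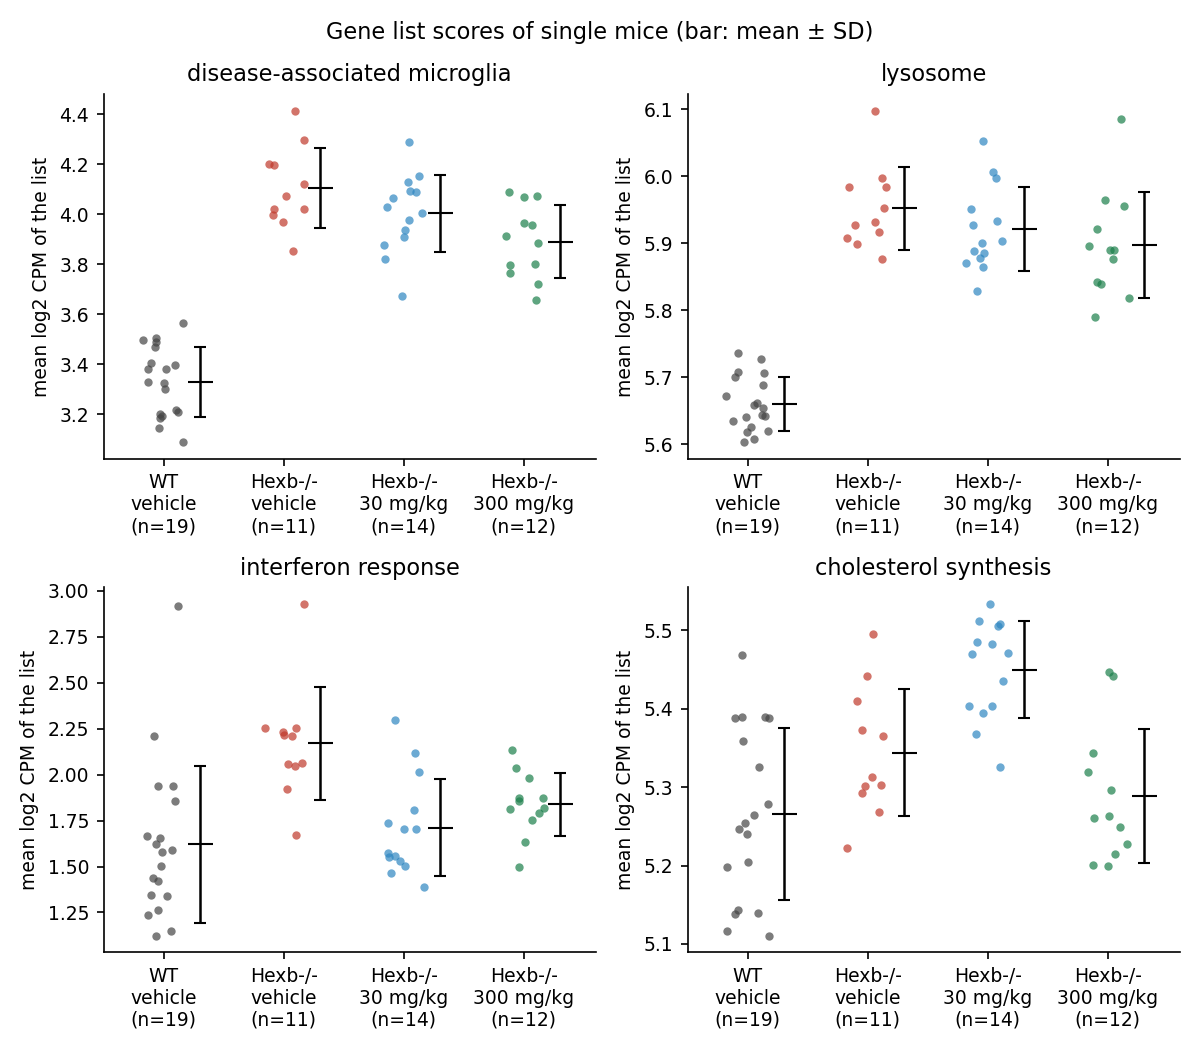
Mean log2 CPM per mouse over 4 gene lists (disease-associated microglia, lysosome, interferon response and cholesterol synthesis), 1 panel per list, for WT (n = 19), Hexb vehicle (n = 11), 30 mg/kg (n = 14) and 300 mg/kg (n = 12); points are mice, and bars give the group mean ± SD. The interferon score is 1.62 ± 0.428 in WT, 2.17 ± 0.307 in Hexb vehicle, 1.71 ± 0.265 at 30 mg/kg and 1.84 ± 0.171 at 300 mg/kg, and the cholesterol synthesis score is 5.45 ± 0.0622 at 30 mg/kg against 5.29 ± 0.0855 at 300 mg/kg.

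Some interferon-response, antigen presentation, astrocyte and endothelial genes rose by smaller amounts. By permutation the score per mouse was higher for interferon response (adjusted p = 0.00642), reactive astrocytes (0.0179), astrocyte markers (0.00351) and endothelial cells (0.00188). It did not pass for antigen presentation (difference 0.286, adjusted permutation p = 0.208), with 0.166 within the shallower and 0.622 within the deeper libraries. Of 17 measured interferon-response genes, 8 rose and none fell (13 and 0 adjusted over the list alone), including the ubiquitin ligase gene Trim30a (log2 0.77, edgeR adjusted p = 1.54e-05), Lgals3bp (0.82, 0.000118), Ifit3 (0.84, 0.000644) and the membrane tether Bst2 (0.70, 0.0123). Camera gave adjusted p = 6.55e-09 for the list, and adjusted p = 0.0846 with an estimated correlation. Of 13 antigen presentation genes 7 rose (7 adjusted over the list alone), including the class I light chain B2m (153.1 ± 15.2 against 93.2 ± 16.6 CPM, log2 0.72, adjusted p = 9.5e-13), H2-D1 (0.71, 9.48e-09), the immunoproteasome subunit Psmb8 (0.61, 2.95e-06) and H2-K1 (0.56, 3.29e-06), with camera adjusted p = 7.05e-07, and adjusted p = 0.0846 with an estimated correlation. Gfap, the intermediate filament of reactive astrocytes, rose from 414 ± 34.0 to 687.2 ± 61.7 CPM (log2 0.73, adjusted p = 1.31e-20). The oncostatin M receptor gene Osmr (0.55, 1.33e-07), Serpina3n (0.37, 4.14e-06) and Ggta1 (0.54, 0.000327) rose with it, and of 20 reactive astrocyte genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 1.33e-05, and adjusted p = 0.0846 with an estimated correlation). Of 12 general astrocyte markers 3 rose, including Aldoc (0.20, 0.00238) and Slc1a3 (0.21, 0.00915; camera adjusted p = 0.0246, and adjusted p = 0.289 with an estimated correlation). Of 11 endothelial genes 6 rose (9 adjusted over the list alone), including the VEGF receptor Flt1 (0.26, 9.88e-06) and Vwf (0.84, 0.000908), with camera adjusted p = 2.24e-06, and adjusted p = 0.0846 with an estimated correlation.

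Camera called 4 further lists up, none of them with an estimated correlation. Of these, only the lymphocyte score per mouse was higher by permutation (adjusted p = 0.000815). Of 3 measurable lymphocyte genes 2 rose, the T-cell co-receptor Cd4 (log2 1.39, edgeR adjusted p = 0.00022) and the immunoglobulin heavy chain Ighm (0.35, 0.0435; 0.0751 with dissection scores as covariates), while the T-cell receptor gene Trac differed by 0.08 (adjusted p = 0.85; camera adjusted p = 0.0117, and adjusted p = 0.0788 with an estimated correlation). Of 8 measured mitochondrially encoded genes 4 rose, including mt-Nd5 (0.19, 0.000946) and mt-Cytb (0.15, 0.00262), with camera adjusted p = 0.000928, and adjusted p = 0.289 with an estimated correlation (score per mouse, adjusted permutation p = 0.576). These genes made up 6.68 ± 0.586% of counts in WT and 7.32 ± 0.489% in Hexb vehicle. Of 19 cholesterol synthesis genes 4 rose (9 rose and 1 fell adjusted over the list alone): the sterol-sensing transcription factor Srebf2 (0.13, 2.86e-05), Fdft1 (0.18, 0.00384), Nsdhl (0.15, 0.0169) and Dhcr24 (0.11, 0.032). The Dhcr24 call was lost without the WT mouse 13B2, a setting chosen after seeing the data. Camera gave adjusted p = 0.00331 for that list, and adjusted p = 0.425 with an estimated correlation (score per mouse, adjusted permutation p = 0.154). None of the 15 choroid plexus genes passed, with a list median of log2 1.22 (camera adjusted p = 0.0346, and adjusted p = 0.712 with an estimated correlation; score per mouse, adjusted permutation p = 0.418).

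Some members of the oligodendrocyte, inhibitory neuron, synaptic and neuropeptide lists fell, and camera called these lists down only with the preset correlation. The score per mouse was lower by permutation for neuropeptides (adjusted p = 0.000141), inhibitory neurons (0.0294) and synapse (0.0353) but not for myelin (0.121). Of 16 myelin and oligodendrocyte genes 6 fell and none rose (10 and 0 adjusted over the list alone), including the lipid enzymes Fa2h (30.1 ± 6.85 against 42.6 ± 13.3 CPM, log2 -0.49, edgeR adjusted p = 0.00314), Ugt8a (-0.52, 0.00507) and Gal3st1 (-0.29, 0.026) and the cytoskeletal protein gene Ermn (-0.41, 0.0137). Camera gave adjusted p = 6.76e-06 for the list, and adjusted p = 0.359 with an estimated correlation. Of 12 inhibitory neuron genes 3 fell (7 adjusted over the list alone): the GABA-synthesising enzymes Gad1 (-0.23, 0.0336) and Gad2 (-0.27, 0.0496) and the neuropeptide Npy (-0.17, 0.0364), with camera adjusted p = 0.00273, and adjusted p = 0.17 with an estimated correlation. Of 16 synapse genes 2 fell, Syt1 (-0.16, 0.00328) and Snap25 (-0.16, 0.00354), both parts of the vesicle fusion machinery (camera adjusted p = 0.0117, and adjusted p = 0.425 with an estimated correlation). Of 13 neuropeptide and neurotrophin genes 6 fell (7 adjusted over the list alone), including Vgf (-0.16, 0.00126), Scg2 (-0.17, 0.00806) and the substance P precursor Tac1 (-0.36, 0.0158), with camera adjusted p = 0.00131, and adjusted p = 0.0624 with an estimated correlation. Cartpt, also among these 6, fell by more (-0.94) and lies 2.7 Mb from Hexb, where called genes clustered. The list was not tested without Cartpt. After Hexb, the largest single falls were in Lyve1 (log2 -1.34, adjusted p = 0.00127) and Cd163 (-0.82, 0.0192), markers of macrophages at the borders of the brain, in the extracellular matrix gene Frem3 (-1.30, 0.00438), Mctp2 (-1.18, 0.00377), the uroplakin gene Upk1b (-1.01, 0.000253), AW495222 (-1.0, 3.36e-05), the peptide Cartpt (-0.94, 0.00386), and the peptide receptors Glp1r (-0.78, 0.00445) and Trhr (-0.77, 0.0255). Frem3 and Mctp2 had a wider spread in WT (2.11 ± 3.03 and 1.88 ± 2.16 CPM) than their means. Without the WT mouse 13B2, a setting chosen after seeing the data, these calls held with smaller changes for Frem3 (-0.76, 0.00485), Mctp2 (-0.77, 0.0045), Gad1 (-0.16, 0.00703) and Gad2 (-0.17, 0.0144), and for Tac1 (-0.33, 0.023). The thalamus and striatum list had 11 of 12 genes below WT with that mouse (median log2 -0.21) and 4 without it (0.105).

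The other lists were not called by camera between Hexb vehicle and WT. No member passed over all genes among excitatory neurons (camera adjusted p = 0.516), hippocampal subfields (0.46), oligodendrocyte precursors (0.512), activity-dependent genes (0.0961), cell cycle (0.203), thalamus and striatum (0.699), mural cells (0.399), ependyma (0.512) or blood (0.664). Single members passed elsewhere. Eomes, a transcription factor of neuronal progenitors, rose among the immature dentate genes (log2 1.11, edgeR adjusted p = 9e-04; list 0.512). The score per mouse of that list was higher in Hexb vehicle by 0.189 ± 0.0521 (SE; adjusted permutation p = 0.0145). The stress factor Ddit3 rose (0.24, 0.00328) and the asparagine synthetase gene Asns fell (-0.15, 0.0013) in the stress list (0.673), and the cell death genes Bbc3 (0.27, 0.00773) and Bax (0.16, 0.00943) rose in the p53 list, where 3 genes rose and 1 fell (0.312). Among border macrophage genes Ms4a7 rose (0.94, 0.0169; the call was lost with dissection scores as covariates) where Lyve1 and Cd163 fell (0.624).

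In all, 1085 genes were higher and 832 lower in Hexb vehicle than in WT, of which 200 and 42 changed by more than 1.5-fold. The balance of directions depended on libraries. Without the WT mouse 13B2, a setting chosen after seeing the data, 973 genes were higher and 1014 lower. At an unadjusted p under 0.05 there were 4212 genes, against 845 if nothing differed. The largest fitted rise was in Prl (log2 4.11, edgeR adjusted p = 0.00277), followed by Cst7 and then Gh (3.97, 0.00175), both pituitary hormone genes. Their levels rested on few libraries, with Gh at 2.13 CPM in the median vehicle mouse and 267 in the highest, and with DESeq2 their calls were lost (log2 1.49, adjusted p = 0.3 for Prl and 1.40, adjusted p = 0.256 for Gh). The sulfotransferases Sult1c1 (3.6, 5e-04) and Sult1c2 (2.24, 0.0101) and the respiratory chain gene Cox8b (2.07, 0.00472) also had standard deviations above their means in Hexb vehicle. Without the 12 libraries of high choroid plexus score, a setting chosen after seeing the data, 564 genes were higher and 323 lower, and 827 of these 887 were among the 1917 called with all libraries. Within the 37 shallower libraries, also a later choice, 1035 genes passed, 936 of them also called with all libraries, and within the 19 deeper ones 176 passed (157 higher and 19 lower), 164 of them also called with all libraries.

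The second comparison asked what the lower dose, meant mainly to inhibit GBA2, changed against Hexb vehicle. The chemokine gene Cxcl10, which interferon induces, fell from 1.19 ± 0.741 CPM in Hexb vehicle (SD, n = 11) to 0.294 ± 0.199 at 30 mg/kg (n = 14), close to the 0.349 ± 0.251 of WT. That is a 4.22-fold fall (log2 -2.08, SE 0.371, edgeR adjusted p = 0.0102), with all 14 treated mice at or under the vehicle median. Other interferon-response genes were lower with it without passing the test over all genes. Ifit3 measured 4.92 ± 1.0 against 8.93 ± 3.69 CPM (log2 -0.87, adjusted p = 0.122), Trim30a differed by -0.47 (adjusted p = 0.467), Lgals3bp by -0.51 (0.51) and Bst2 by -0.43 (0.744). All 17 interferon-response genes had negative fold changes, 11 of them passing when adjusted over the list alone and none over all genes, with a list median of log2 -0.47. Camera called the list down (adjusted p = 3.83e-15; adjusted p = 0.0935 with an estimated correlation). The mean interferon score per mouse was lower by 0.458 ± 0.117 (SE; adjusted permutation p = 0.00465, two-sided), and by 0.383 and 0.673 within the shallower and the deeper libraries. The deeper libraries held only 3 vehicle mice, among them 10D2, which had the highest interferon score of the vehicle mice (2.93).

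Antigen presentation genes stood lower with the interferon genes and cholesterol synthesis genes stood higher, without a gene passing over all genes. H2-D1 differed by log2 -0.35 (edgeR adjusted p = 0.455), Psmb8 by -0.39 (0.451), H2-K1 by -0.32 (0.467) and B2m by -0.24 (0.467), and 5 of 13 antigen presentation genes passed adjusted over the list alone (camera adjusted p = 1.16e-08, and adjusted p = 0.128 with an estimated correlation). Their score per mouse differed by -0.29 (adjusted permutation p = 0.154), and by -0.212 without the vehicle mouse 10D2. Of 19 cholesterol synthesis genes 18 had positive fold changes and 3 passed adjusted over the list alone, with Nsdhl at log2 0.17 (adjusted p = 0.467) and Fdft1 at 0.08 (0.801). Camera called that list up (adjusted p = 6.63e-09; adjusted p = 0.128 with an estimated correlation), and the score per mouse was higher by 0.106 ± 0.0296 (SE; adjusted permutation p = 0.0107), by 0.136 within the shallower but 0.039 within the deeper libraries. The microglial and complement genes that had risen most against WT differed little from vehicle. Trem2 differed by -0.03 (adjusted p = 0.924), Cd68 by -0.09 (0.827), C1qb by -0.09 (0.798) and Cst7 by -0.39 (0.772), and the astrocyte gene Gfap by -0.11 (0.705). The hemoglobin list had a median of log2 -1.21, with all 5 genes passing adjusted over the list alone (Hba-a2 -1.28, adjusted p = 0.569 over all genes; camera adjusted p = 0.000216, and adjusted p = 0.21 with an estimated correlation). The ependymal list, with Foxj1 at -0.47 (adjusted p = 0.652), had camera adjusted p = 0.000125, and adjusted p = 0.21 with an estimated correlation.

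Of the other lists, camera called the mitochondrially encoded genes up (adjusted p = 0.00116, and adjusted p = 0.417 with an estimated correlation) and 10 lists down, in each of which no gene passed over all genes except Cxcl10 among the cytokines. These were reactive astrocytes (0.00011, and 0.2 with an estimated correlation), complement (0.00102 and 0.324), myelin (0.00283 and 0.599), disease-associated microglia (0.00485 and 0.417), choroid plexus (0.00485 and 0.63), cytokines (0.00709 and 0.128), lysosome and endothelial cells (0.0269 each, with 0.599 and 0.542), and mural cells and border macrophages (0.0424 each, with 0.654 and 0.542). Cxcl10 was the only gene called by edgeR, with 1132 genes at an unadjusted p under 0.05; DESeq2 called 5 genes (Cxcl10, Ifit3, Gbp5, Phf11d and Spop, the last 3 chosen after their values were seen) and limma-voom 0. The call was lost without the vehicle mouse 9B3 or the vehicle mouse 9B5, with only the groups compared (log2 -2.09, adjusted p = 0.0568) and with the animal code prefix as a random effect (-2.08, 0.187). In settings chosen after seeing the data it was also lost within the shallower (-1.43, 0.717) and the deeper libraries (-3.27, 0.59), without the libraries of high choroid plexus score (-1.49, 1) and without those high in Gh or Prl (-2.05, 0.283). Simulated changes of 1.5-fold in this comparison were recovered in 74% of genes and of 2-fold in 84%. The simulation called 128 genes, and with that many calls the adjustment passes larger p-values than where only Cxcl10 was called. These shares thus do not tell how many real changes of that size would be missed here. Gba2 (log2 0.03, adjusted p = 0.869) and Ugcg (0.06, 0.834) did not pass, nor did Hexa, Gm2a or Gba (adjusted p = 0.952, 0.942 and 0.931).

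The third comparison asked the same of the higher dose, meant to inhibit GBA2 and GCS. Microglial and complement lists stood lower than in Hexb vehicle, by small amounts spread over many genes. Cst7 measured 1.76 ± 0.676 CPM (SD, n = 12) against 3.18 ± 0.980 in Hexb vehicle (n = 11; log2 -0.86, edgeR adjusted p = 0.682), Cd68 differed by -0.24 (0.88), Trem2 by -0.15 (1), C1qb by -0.18 (0.989) and C1qa by -0.17 (1). None of these genes passed over all genes. Of 16 complement genes 15 had negative fold changes and 5 passed adjusted over the list alone, with a median of log2 -0.18 (camera adjusted p = 1.17e-11, and 0.026 with an estimated correlation). Of 23 disease-associated microglia genes 20 were negative and 3 passed adjusted over the list alone, with a median of -0.14 (camera adjusted p = 1.46e-10, and 0.026 with an estimated correlation). These were the 2 lists whose calls held with an estimated correlation. The score per mouse was lower by 0.194 ± 0.0552 for complement (SE; adjusted permutation p = 0.0109) and by 0.215 ± 0.0641 for disease-associated microglia (0.0155), the latter by 0.169 within the shallower and 0.342 within the deeper libraries. Only 3 vehicle mice were among the deeper libraries, and 1 of them, 10D2, had the highest disease-associated microglia score of the vehicle mice (4.42).

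Interferon-response genes were lower at this dose too. Cxcl10 measured 0.323 ± 0.174 CPM (log2 -1.93, edgeR adjusted p = 0.0901), Ifit3 differed by -0.69 (0.88) and Trim30a by -0.42 (1). All 17 interferon-response genes had negative fold changes, 2 passing adjusted over the list alone (camera adjusted p = 1.17e-11, and adjusted p = 0.0941 with an estimated correlation), and the score per mouse was lower by 0.331 ± 0.105 (SE; adjusted permutation p = 0.0109), by 0.194 and 0.667 within the shallower and the deeper libraries. The value within the deeper libraries again rests on 3 vehicle mice, with 10D2 among them. The lysosome list was called down with a median of log2 -0.05 (camera adjusted p = 9.05e-10, and adjusted p = 0.1 with an estimated correlation). Its score per mouse differed by -0.055 ± 0.0294 and did not pass (SE; adjusted permutation p = 0.21). Cholesterol synthesis genes, higher at 30 mg/kg, were called down here (camera adjusted p = 3.91e-05, and adjusted p = 0.357 with an estimated correlation), with Dhcr24 at -0.16 (adjusted p = 0.682), Fdft1 at -0.17 (0.989) and Srebf2 at -0.09 (0.682). The cholesterol synthesis score per mouse differed by -0.0551 ± 0.0347 and did not pass (SE; adjusted permutation p = 0.304). Gfap differed by -0.19 (0.682) and the hemoglobin gene Hba-a2 by -1.43 (1). Camera also called down blood (adjusted p = 6.97e-05, and 0.183 with an estimated correlation), antigen presentation (0.00104 and 0.419), reactive astrocytes (0.00597 and 0.419), cytokines (0.00799 and 0.0941), thalamus and striatum (0.0297 and 0.571), and ependyma and border macrophages (0.0302 each, with 0.561 and 0.505), and it called the mitochondrially encoded genes up (0.0115 and 0.554). The antigen presentation score per mouse differed by -0.0673 ± 0.133 (SE; adjusted permutation p = 0.767). Its sign turned within the shallower libraries (0.114, against -0.521 within the deeper), with dissection scores as covariates (0.0096) and without the vehicle mouse 10D2 (0.0105).

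No gene passed the edgeR test at 300 mg/kg against Hexb vehicle, with 623 genes at an unadjusted p under 0.05 and Cxcl10 nearest the threshold. DESeq2 called Cxcl10 alone (adjusted p = 0.0454) and limma-voom called 0. Cxcl10 passed the edgeR test when the vehicle mouse 10D1 or the vehicle mouse 11B3 was left out. Simulated changes of 1.5-fold were recovered in 76% of genes here and of 2-fold in 94%. That simulation called 142 genes, so its adjustment passed larger p-values than the real fit, where no gene passed. The shares thus do not tell how many real changes of that size would be missed. Gba2 (log2 -0.02) and Ugcg (-0.01) did not pass, nor did Hexa, Gm2a or Gba (adjusted p = 1 for each of the 5).

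Both doses were set against the same 11 vehicle mice, so their fold changes share chance. Over 16909 genes the fold changes of the doses correlated with r = 0.578, where simulated doses without any effect gave 0.545 (95% of simulations 0.332 to 0.708). The covariance was 0.0102 against 0.0109 simulated (SD 0.00341), and with the vehicle mice split between the doses the correlation was -0.000267. Genes are not independent replicates in these correlations. Fold changes of Hexb vehicle against WT and of each dose against vehicle also share the vehicle mice. Of the 1917 genes that differed between Hexb vehicle and WT, 1568 (81.8%) had the opposite sign at 30 mg/kg and 1649 (86.0%) at 300 mg/kg. With limma calls (1850 genes) the shares were 81.9% and 85.9%. Simulated doses that did nothing gave 70.4% (52.3 to 86.9) and 69.3% (46.8 to 85.8). The simulations called 3152 genes on average, a longer list than the observed one. The shares are thus not directly comparable and do not decide whether the doses moved genes toward WT. With the vehicle mice split, the fold changes over 16909 genes correlated with -0.123 at 30 mg/kg and -0.0544 at 300 mg/kg.

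The fourth comparison set the doses against each other and asked what differs once GCS is also meant to be inhibited. Genes of cholesterol synthesis were lower at 300 mg/kg. Nsdhl, a sterol dehydrogenase, measured 27.5 ± 1.71 CPM at 300 mg/kg (SD, n = 12) and 33.1 ± 2.32 at 30 mg/kg (n = 14; log2 -0.27, SE 0.0453, edgeR adjusted p = 0.00298). Fdft1, squalene synthase, measured 73.6 ± 5.62 against 87.4 ± 8.12 (log2 -0.25, SE 0.0469, adjusted p = 0.0106), Hmgcs1, an early enzyme of the pathway, 195 ± 12.8 against 228.7 ± 14.8 (-0.23, SE 0.0441, 0.0106), and Dhcr24, which reduces sterols to cholesterol, 96.8 ± 4.53 against 109.8 ± 5.42 (-0.18, SE 0.0375, 0.0309). Of the 12 mice at 300 mg/kg, 1 lay above the 30 mg/kg median for Fdft1 and none for the other 3 genes. The fifth gene called was Nbr1, a selective autophagy receptor, at 182 ± 5.26 against 199.3 ± 8.14 CPM (log2 -0.13, SE 0.0238, adjusted p = 0.00695). Srebf2, the transcription factor that drives the pathway, differed by -0.10 (adjusted p = 0.101). By edgeR no gene was higher at 300 mg/kg, while limma-voom called 3 higher.

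All 19 cholesterol synthesis genes had negative fold changes between the doses, with a median of log2 -0.16. Of these 4 fell over all genes and 11 adjusted over the list alone, and the list was the only one whose camera call held with an estimated correlation (adjusted p = 2.21e-26, and 0.00186 with an estimated correlation). The score per mouse was lower by 0.161 ± 0.0298 at 300 mg/kg (SE; adjusted permutation p = 0.000742), by 0.165 within the shallower and 0.157 within the deeper libraries. Camera called 6 further lists, each with adjusted p = 0.975 with an estimated correlation: myelin up (camera adjusted p = 0.000921), lysosome down (0.00414), disease-associated microglia down and antigen presentation up (0.00977 each), complement down (0.0137) and mural cells up (0.0172). Gba2 (log2 -0.05) and Ugcg (-0.07) did not pass (edgeR adjusted p = 0.968 for each). The interferon score differed by 0.127 ± 0.0864 (SE; adjusted permutation p = 0.358) and the disease-associated microglia score by -0.112 ± 0.0589 (0.197), so neither score differed between the doses by permutation. At an unadjusted p under 0.05 there were 870 genes, DESeq2 called 6 (the 5 genes and Srebf2), all lower, and limma-voom 15, of which 12 were lower and 3 higher. The edgeR fits with dissection scores as covariates (7 genes) and with 4 surrogate variables (10 genes, a setting chosen after seeing the data) each held 1 higher gene. Without the libraries of high choroid plexus score, a setting chosen after seeing the data, no gene passed the edgeR test (Nsdhl log2 -0.25, adjusted p = 0.0719), with 631 genes at an unadjusted p under 0.05. None passed within the shallower or the deeper libraries alone, with 850 and 528 genes at an unadjusted p under 0.05, and with depth as a factor the 5 genes were called.

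**Figure D3:**
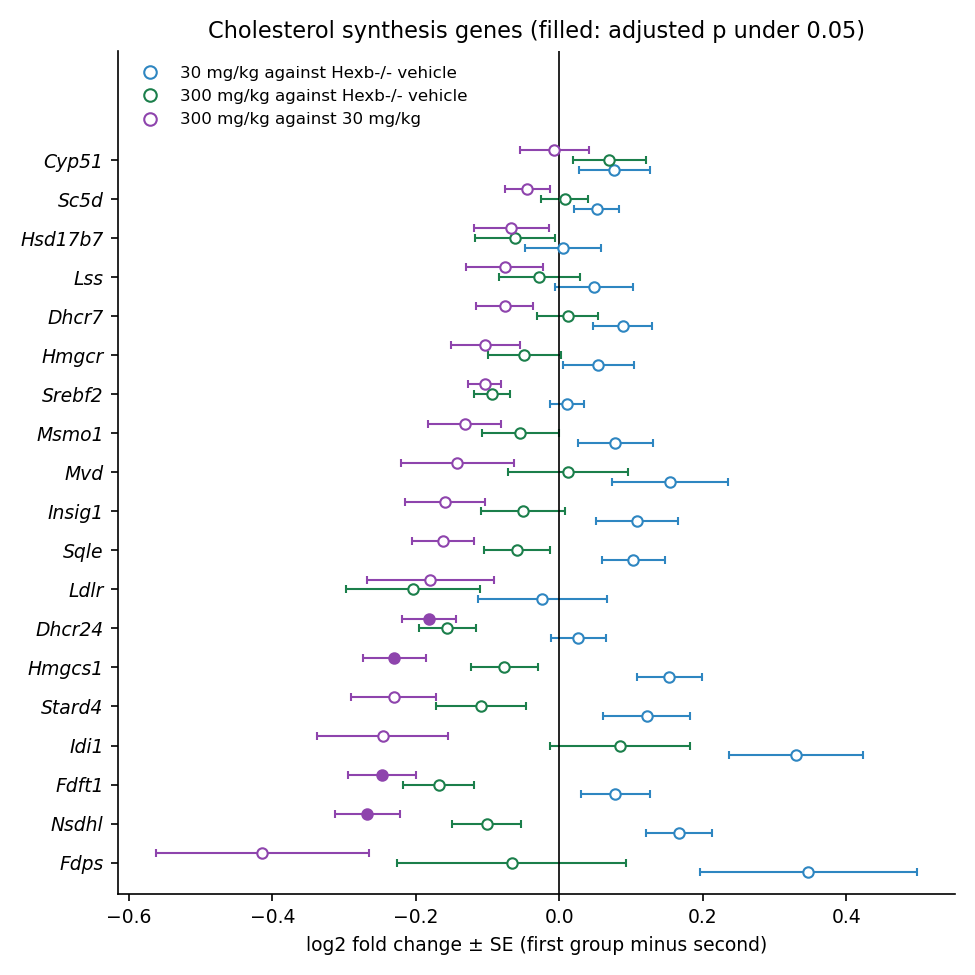
Log2 fold change ± SE of the 19 cholesterol synthesis genes in 3 comparisons, 30 mg/kg against Hexb vehicle, 300 mg/kg against Hexb vehicle and 300 mg/kg against 30 mg/kg; filled points pass an edgeR adjusted p of 0.05. Filled points are Nsdhl, Fdft1, Hmgcs1 and Dhcr24 in the comparison of the doses, where all 19 genes lie below 0.

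The last 2 comparisons asked what still differed from WT at each dose. Against WT, the 30 mg/kg mice kept high levels of microglial, complement and lysosomal genes. Cst7 was higher by log2 3.68 (edgeR adjusted p = 3.08e-19), Ly9 by 3.10 (1.14e-19), Cd22 by 2.70 (9.54e-17), the macrophage lysozyme Lyz2 by 1.86 (1.26e-18), the inhibitory receptor Pirb by 1.78 (7.04e-08) and Trem2 by 1.16 (3.37e-27). The phagocytic receptor Clec7a (2.13, 2.52e-11) and the immune receptor Treml2 (2.08, 6.77e-12) were also among the 10 largest rises, with the pituitary hormone genes Gh (3.79, 0.00237), Prl (3.45, 0.012) and Pomc (2.16, 0.00418). Of the lists, 32 of 43 lysosome, 15 of 23 disease-associated microglia and 12 of 16 complement genes rose, and none fell (camera adjusted p = 2.66e-06 with an estimated correlation for each), as did 2 of 5 cytokine genes (0.0136 with an estimated correlation). Cholesterol synthesis genes also stood above WT, with 13 of 19 risen (14 adjusted over the list alone), including Srebf2 (0.14, 1.06e-06) and Nsdhl (0.32, 2.22e-08; camera adjusted p = 3.22e-13, and 0.0253 with an estimated correlation). Of 8 mitochondrially encoded genes 7 rose, including mt-Nd5 (0.26, 1.04e-06; 0.0453 with an estimated correlation). Of 11 endothelial genes 4 rose (camera adjusted p = 0.000342, and adjusted p = 0.215 with an estimated correlation). Gfap was higher by 0.62 (1.26e-18), and 4 of 20 reactive astrocyte genes rose (0.0488, and adjusted p = 0.488 with an estimated correlation). Interferon-response genes did not differ from WT by the test (0 of 17 genes; camera adjusted p = 0.344), and of 13 antigen presentation genes 3 rose, with a list mean of log2 -0.07 where the median was 0.13.

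Myelin genes fell at 30 mg/kg against WT, 12 of 16 and none rising, including Ugt8a (log2 -0.65, edgeR adjusted p = 0.000157; camera adjusted p = 7.35e-13, and adjusted p = 0.118 with an estimated correlation). Among inhibitory neuron genes 5 of 12 fell and 1 rose, with Npy at -0.22 (0.00239; camera adjusted p = 0.00564, and adjusted p = 0.215 with an estimated correlation), and among neuropeptide genes 4 of 13 fell and 1 rose (0.00564, and adjusted p = 0.0935 with an estimated correlation). Blood and activity-dependent genes were called down by camera (0.0464 each, with adjusted p = 0.488 and 0.547 with an estimated correlation). Lyve1 (-1.53, 7.84e-05), Cd163 (-0.99, 0.00231), AW495222 (-1.08, 1.25e-06) and the synaptic vesicle gene Sv2c (-0.77, 2.01e-07) were among the largest falls, with Frem3 (-1.11, 0.00818), Cartpt (-1.02, 0.000673), Upk1b (-0.80, 0.00147), the striatal receptor gene Gpr6 (-0.93, 0.0148) and the transcription factor Six3 (-2.11, 0.0272). The Six3 value rested on the WT mouse 13B2 (WT 4.17 ± 13.9 CPM with a median of 0.987). Without it, a setting chosen after seeing the data, Six3 differed by -0.03 (adjusted p = 0.972), Gpr6 by -0.70 (0.0388), Frem3 by -0.57 (0.0261) and Npy by -0.23 (0.00142), and 5 of 12 inhibitory neuron genes still fell. The thalamus and striatum list median went from -0.25 to 0.07. In all 958 genes were higher and 614 lower, with 863 and 788 when library totals were the only scaling. The fixed genes Hexa (0.38, 8.02e-13), Gm2a (0.22, 7.56e-07) and Gba (0.18, 6.73e-05) stayed above WT.

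At 300 mg/kg against WT the microglial, complement and lysosomal genes were again higher. Cst7 was higher by log2 3.21 (edgeR adjusted p = 1.14e-15), Ly9 by 2.88 (1.84e-17), Cd22 by 2.69 (5.36e-16), Lyz2 by 1.69 (4.24e-16), the surface receptor Cd48 by 1.32 (1.78e-06) and Trem2 by 1.04 (8e-24). Treml2 (1.92, 6.54e-10) and Clec7a (1.74, 1.02e-07) were also among the 10 largest rises, with Sult1c1 (3.68, 0.000424), Cox8b (2.03, 0.0076) and the nicotinic receptor subunit Chrnb4 (1.73, 0.0329), whose standard deviations at 300 mg/kg exceeded their means for Sult1c1 and Chrnb4. Of the lists, 31 of 43 lysosome, 13 of 23 disease-associated microglia and 11 of 16 complement genes rose and none fell (camera adjusted p = 8.28e-06 with an estimated correlation for each), with 3 of 5 cytokine genes (0.00516 with an estimated correlation). None of the 19 cholesterol synthesis genes passed (Srebf2 0.04, adjusted p = 0.354; camera adjusted p = 0.515). Of 8 mitochondrially encoded genes 7 rose, including mt-Cytb (0.18, 0.000326; camera adjusted p = 7.1e-08, and adjusted p = 0.0649 with an estimated correlation). Gfap was higher by 0.54 (3.07e-15), with 5 of 20 reactive astrocyte genes (0.000966, and adjusted p = 0.215 with an estimated correlation), 4 of 11 endothelial genes (4.62e-06 and 0.109) and 4 of 13 antigen presentation genes (8.62e-05 and 0.215). Camera also called up interferon response (1 gene rose; 0.0302, and adjusted p = 0.563 with an estimated correlation), astrocyte markers (0.0369 and 0.31) and lymphocytes (0.0444 and 0.152).

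Inhibitory neuron genes fell at 300 mg/kg against WT, 7 of 12, including Gad2 (log2 -0.35, edgeR adjusted p = 0.013; camera adjusted p = 4.7e-05, and adjusted p = 0.0649 with an estimated correlation). Of 13 neuropeptide genes 4 fell, including Vgf (-0.17, 0.000656; 0.00254, and adjusted p = 0.0649 with an estimated correlation). Of 16 myelin genes 2 fell and 12 did so adjusted over the list alone (1.03e-06, and adjusted p = 0.31 with an estimated correlation). Camera called synapse (0.0369 and 0.542 with an estimated correlation) and blood (0.0444 and 0.525) down. Lyve1 (-1.90, 1.41e-05), Cd163 (-1.19, 0.000923), AW495222 (-1.28, 1.72e-07) and Sv2c (-0.77, 1.17e-06) were among the largest falls, with Frem3 (-1.21, 0.00987), Upk1b (-0.96, 0.00052), Cartpt (-0.94, 0.00446), Trhr (-0.74, 0.0363) and the dopamine receptor Drd2 (-0.73, 0.00801). Without the WT mouse 13B2, a setting chosen after seeing the data, Drd2 (-0.49, 0.00487), Gad2 (-0.24, 4e-04) and Frem3 (-0.66, 0.0183) fell by less, and of 12 inhibitory neuron genes 7 fell and 1, Pvalb, rose (0.18, 0.0387). The thalamus and striatum list, with 11 of 12 genes below WT and a median of -0.47 with all mice, had 6 and a median of -0.02 without it. In all 644 genes were higher and 501 lower. Without the WT mouse 13B2 the counts were 557 and 558, and with library totals as the only scaling 582 and 565. Hexa (0.31, 4.46e-09), Gm2a (0.19, 5.41e-05) and Gba (0.14, 0.00549) stayed above WT.

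Most genes that separated Hexb vehicle from WT kept their direction in treated mice. Of these 1917 genes, 1900 (99.1%) had the same sign against WT at 30 mg/kg and 1904 (99.3%) at 300 mg/kg. The comparisons share the WT mice, and doses simulated at the WT level gave 60.4% (43.8 to 80.1) and 58.6% (42.9 to 71.8). With the WT mice split between the comparisons the shares were 93.7% and 95.5% of 1319 genes on average. Of genes higher than WT, 624 were called in both Hexb vehicle and 30 mg/kg, 496 in both Hexb vehicle and 300 mg/kg, and 432 in all 3 groups. Independent lists would share 61.5 and 41.3. Of genes lower than WT the counts were 333, 376 and 235, with 30.2 and 24.7 for independent lists. Groups simulated without any effect shared 0 calls. Hardly any gene passes the adjustment without an effect, so this does not tell how much overlap the shared WT mice bring. With the WT mice split between the comparisons the mean overlaps were 314.6 higher and 106 lower for 30 mg/kg (25.2 and 9.53 for independent lists) and 236.8 and 116.2 for 300 mg/kg (16.1 and 8.44).

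A position between WT (0) and Hexb vehicle (1) was computed for each dose over genes chosen in one part of the control mice and scored on the other part. The 30 mg/kg mice lay at 0.897 (95% bootstrap interval 0.746 to 1.06) and the 300 mg/kg mice at 0.848 (0.710 to 1.03), with a difference of -0.049 (-0.190 to 0.119). Both intervals include 1, but at 300 mg/kg the upper end fell below 1 with a stricter signature (0.971), with genes weighted by fold change (0.995) and without 11E4 and 11E5 (0.986). A shift toward WT over the whole set of genes was thus not shown at 30 mg/kg and depended on the setting at 300 mg/kg, and a difference between doses was not shown. With the disease-associated microglia list as the only genes, the positions were 0.868 and 0.724 (0.559 to 0.910), and the difference was -0.145 (-0.302 to -0.0017). This interval ends just under 0, while permutation of the same list's scores between the doses gave p = 0.0687 before adjustment, so the difference between doses was not settled for this list.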

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

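The tests of dissection, myelin content, code number and depth for the cholesterol synthesis genes, and the fits within depth clusters and without high-choroid or high-Gh or Prl libraries, were chosen only after the result was seen. Between the doses 5 genes differed in the direct test of 300 against 30 mg/kg, which is why they are listed here: Nsdhl (log2 -0.27), Nbr1 (-0.13), Fdft1 (-0.25), Hmgcs1 (-0.23) and Dhcr24 (-0.18). The cholesterol synthesis list also differed (adjusted p = 0.00186 with an estimated correlation), with all 19 genes lower at the higher dose.

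The cholesterol synthesis difference was weighed against technical sources. With dissection scores as covariates the list's median was log2 -0.158 where it was -0.159 without them. With the code number as a factor it was -0.163, and within the 37 shallower libraries -0.13. None of these differences between libraries thus carries the whole pattern. The library index runs mostly by group and hardly overlaps between the doses, so its part cannot be told apart from dose and was not tested. With fewer mice the calls ended: 0 of 19 members were called by edgeR within the shallower libraries (Nsdhl log2 -0.27, adjusted p = 0.0863) and 0 within the 19 deeper (-0.27, adjusted p = 1; list median -0.149), with 850 and 528 of all genes at an unadjusted p under 0.05. Oligodendrocytes make much cholesterol, yet the myelin list moved the other way, with a median of +0.115, which argues against lower myelin content as the source.

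Without the libraries of high choroid plexus score the median was -0.144, but 0 genes were called by edgeR with fewer mice (Nsdhl -0.25, adjusted p = 0.0719; 631 genes at an unadjusted p under 0.05), and without the libraries high in Gh or Prl only Nsdhl was (-0.29, adjusted p = 0.00855). A hypothesis that stays open, found and tested on the same data, is that inhibiting GCS at the higher dose may lower sterol synthesis or undo a rise brought by GBA2 inhibition at the lower dose; a group with a GCS inhibitor alone would test it.

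For each comparison, 100 splits of the same mice, the real one included, were tested for as many called genes. For Hexb vehicle against WT (1 of the splits, 1917 genes, highest other 409) and 300 against 30 mg/kg (1, 5 genes, highest other 2) only the real split called as many genes. The same held for 30 mg/kg against WT (1, 1572 genes, highest other 9) and 300 mg/kg against WT (1, 1145 genes, highest other 26). This argues against chance differences between single mice, as far as 100 splits can. Splits of whole code prefixes were not made, so chance between prefixes is left open. Such chance is not argued against for 30 mg/kg against Hexb vehicle (8 of the splits, 1 gene, highest other 2). For 300 mg/kg against Hexb vehicle the splits cannot decide. The real count was 0 by edgeR, so all 100 splits called as many (highest other 1). There 623 genes had an unadjusted edgeR p under 0.05, and DESeq2 called 1 gene and limma-voom 0.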

How the results depend on the processing

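The fits without high-choroid libraries, without 13B2, without libraries high in Gh or Prl, within the shallower or the deeper libraries, with surrogate variables, with depth as a factor and with sex and dissection ratios together were chosen only after seeing the data. No paired analysis was possible because replicate numbers given in accession order only name samples. Animal code prefixes hold 1 group each except 11F. With the prefix as a random effect limma-voom called 1702, 1359 and 873 genes against WT and 4 between the doses. Of these, 1628, 1327, 861 and 4 were also called in the main fit. The cause of each difference below was not tested.

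Counts against WT were lower in some fits on fewer libraries. Whether the number of mice or the choice of mice removed lies behind this was not tested. Between Hexb vehicle and WT (1917 genes) the count was 1035 within the 37 shallower and 176 within the 19 deeper libraries and 887 without those of high choroid plexus score, and it ran in leave-one-out from 1599 (without 10D2, vehicle) to 2148 (without 10D1, vehicle). For 30 mg/kg against WT (1572) it was 602 within the shallower, 168 within the deeper and 933 without the high Gh or Prl libraries, and for 300 mg/kg against WT (1145) 601, 72 and, without the high-choroid ones, 753. The other 19 of 22 settings stayed within 1.5-fold in each of these.

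For 30 mg/kg against Hexb vehicle edgeR called 1 gene. DESeq2 called 5, the code number 2, and limma-voom, the CPM filter, only the groups compared, the code prefix as random effect, and fits within the shallower, within the deeper and without high-choroid or high Gh or Prl libraries 0. With 1 mouse left out it was 0 without 9B3 or 9B5 (vehicle) and 3 without 11F3 or 12D1 (WT), 11F2 (vehicle) or 10F1 (30 mg/kg). Cxcl10 had log2 -1.96 (adjusted p = 0.0752) with voom, -2.09 (0.0568) with only the groups compared and -2.08 (0.187) with the prefix, and was not tested under the CPM filter. For 300 mg/kg against Hexb vehicle edgeR called 0 and DESeq2 1; leave-one-out gave 0 to 1 (without 10D1 or 11B3, vehicle). For 300 against 30 mg/kg edgeR called 5, limma-voom 15 (3 of them higher), 4 surrogate variables 10, the fits within the shallower, within the deeper and without high-choroid libraries 0, and without high Gh or Prl ones 1; leave-one-out gave 4 to 8 (8 without 10F4, 30 mg/kg).

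With an estimated correlation the lists called went from 17 to 4 (Hexb vehicle against WT), 16 to 0 (30 mg/kg against vehicle), 13 to 2 (300 mg/kg against vehicle), 7 to 1 (300 against 30 mg/kg), 13 to 6 (30 mg/kg against WT) and 16 to 4 (300 mg/kg against WT). With fry they were 1, 2 and 1 in the comparisons against vehicle and between doses, and with dissection covariates 10 at 30 mg/kg against vehicle. The position at 300 mg/kg was 0.724 with the disease-associated microglia list, and its interval ended under 1 with a stricter signature (0.971), weights (0.995) or without 11E4 and 11E5 (0.986). Without 13B2, Six3 (-2.11 at 30 mg/kg against WT) went to -0.03 (adjusted p = 0.972), and the calls of Dhcr24 (0.0763) and Ighm (0.0633) between Hexb vehicle and WT were lost. No named gene reversed.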

Other observations

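The tests of called genes near Hexb, of the general genotype effect there, of the share of called genes near Hexb, and of the shared genotype effect on Gh were chosen only after the result was seen. Glycosphingolipid genes moved both ways between Hexb vehicle and WT, 7 of 44 up and 3 down (camera adjusted p = 0.381), with Sgpl1, which breaks down sphingosine phosphate (log2 0.28, edgeR adjusted p = 6.97e-08), and the sialidase Neu1 (0.19, 2.72e-06) up. Among cholesterol export genes Apoe (0.25, 3.48e-08) and the receptor-degrading ligase Mylip (0.19, 0.00909) rose and the transporters Abcg4 (-0.14, 0.00107) and Abcg1 (-0.10, 0.0198) fell (list 0.512). Of 14 homeostatic microglia genes 3 rose and 2 fell (0.699), with Fcrls (0.47, 7.41e-08) and Siglech (0.34, 0.000144) up and Selplg (-0.27, 0.000129) and Slc2a5 (-0.48, 0.000314) down.

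Called genes clustered around Hexb on chromosome 13. Within 10 Mb, 23 of 110 tested genes (20.9%) differed between Hexb vehicle and WT, 10 higher and 13 lower, against 11.4% on other chromosomes. Among them were Marveld2 (log2 1.07, edgeR adjusted p = 1.54e-05), Naip6 (0.94, 0.00524), F2r (0.83, 8.05e-09) and Iqgap2 (0.55, 4.56e-08), chosen after their values were seen, with AW495222 (-1.0), Cartpt (-0.94) and Sv2c (-0.75, 2.36e-06). Cartpt also counts among the neuropeptide genes that fell against WT in Hexb vehicle and at both doses. Within 5 Mb 22.7% were called (17 of 75), against 3.51% at 10 to 20 Mb (2 of 57) and 9.69% further out on the chromosome (44 of 454). The odds ratio was 7.96 against the 10 to 20 Mb bin (95% interval 1.76 to 74.1, p = 0.00204), whose rate was low, 2.72 against the chromosome beyond 20 Mb (1.37 to 5.26, p = 0.00277) and 2.27 against other chromosomes (1.24 to 3.97, p = 0.00541). Of the 23 called genes 15 (65.2%) were also called at both doses against WT, where 34.5% of called genes elsewhere were. From the odds ratios, a strain variant carried with the targeted locus may lie behind some of them.

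A general genotype effect with no tie to the locus is argued against for these genes by the odds ratio of 2.06 within 10 Mb (p = 0.00374). Whether such a variant has a part in the whole genotype pattern stays open. This ratio, with rises and falls alike, met what had been set beforehand for it. Its lower bound of 1.24 lay under 1.5, which had been set beforehand as an outcome against it. The preset rule thus does not decide, and reading the bound as imprecision was a later choice. Of the called genes 1.2% lie within 10 Mb. Only 110 tested genes lie in that window and 1886 genes were called elsewhere, so this share had to be small. It cannot test such a variant as the source of most of the pattern, and no conclusion is drawn from it. Effects on distant genes were not tested. Genotyping this interval against the WT strain would test for such a variant.

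Gh, Prl and Pomc reads may come from pituitary tissue in some samples. Cga, the pituitary hormone subunit gene, followed Gh over the 56 libraries (Spearman rho 0.708, p = 1e-05, the smallest that permutation can give), and rho was 0.625 within the 19 WT libraries. With Gh as reference, rho was 0.804 for Prl, 0.636 for Pomc, 0.469 for Pou1f1, 0.391 for Tshb and 0.329 for Ghrhr (adjusted p = 0.022). It was 0.202 for Fshb, 0.177 for Tbx19, 0.128 for Pitx1 and 0.0755 for Lhb, which did not pass (adjusted p = 0.196, 0.241, 0.384 and 0.578) and had 26, 54, 34 and 7 counts over all libraries. The highest values were 267 CPM for Gh, 315 for Prl, 32.6 for Pomc and 8.86 for Cga. A genotype effect shared by all Hexb mice stays open. Their median Gh of 2.46 CPM lay within the WT 90th percentile of 5.0 but above the WT median of 0.652, with 2.13, 3.16 and 2.54 in Hexb vehicle, 30 mg/kg and 300 mg/kg.

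The libraries of 300 mg/kg mice 11E4 and 11E5 carry a library index that lies among those of Hexb vehicle. Their disease-associated microglia scores were 3.72 and 3.96, with vehicle mice at 3.85 to 4.42 and the other 300 mg/kg mice at 3.66 to 4.09, so the lower score argues against both being vehicle mice. Sex is not in the labels. Ddx3y was the high marker in 10 WT, 4 Hexb vehicle, 6 30 mg/kg and 4 300 mg/kg libraries. Xist was high in 8, 6, 8 and 8 in the same order. WT 12D2 had reads of both (log2 CPM 4.55 for Xist and 5.15 for Ddx3y), and vehicle mouse 11B3 was low in both (-0.22 and -0.13). These libraries were left out of the interaction test but stayed in the main fits. An interaction of the Xist to Ddx3y class with each of 4 comparisons gave 0 genes by edgeR over 54 libraries, with smallest adjusted p = 0.314, 1, 1 and 0.99, and 1285, 489, 747 and 637 genes at an unadjusted p under 0.05; no other tool was run for it.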
